A study of Mus musculus with 16 samples.

How the data were processed

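Total RNA from whole pancreas of 16 mice was made into strand-specific libraries with the TruSeq Stranded Total RNA kit, per the labels' protocols. There were 4 animals in each of 4 genotype groups (WT, DC, MC and DMC), which the labels call independent biological replicates, and groups were read from the sample labels. Per the labels' protocols the mice were 6 to 10 weeks old, received caerulein at 50 ug/kg in 4 hourly intraperitoneal injections, 3 times a week for 3 weeks, and were collected 5 days after the last injection. Pancreas without caerulein was not analysed here.

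Per the submitters' processing notes, the authors aligned reads with STAR 2.6.0b to GRCm38 and used DESeq2, whose version is not given. The read counter, the annotation release and the gene filter are not given in the sources used here. The deposited values are normalized count signal, gene counts that the authors divided by a size factor per library, for 15156 genes in 16 columns. Within each library 100% of values were whole multiples of a single step, within a tolerance of 0.01 reads, so reads were recovered by dividing by that step. Recovered reads came to 13481063 to 23728309 per library and size factors to 0.566 to 1.63. Every gene in the table had at least 33 reads over all libraries and reads in at least 4 of them, so genes below that could not be examined. Gene coordinates came from the GENCODE mouse annotation, release 21, on GRCm38, in which 15152 of the gene identifiers were found and 4 were not. Genes absent from the table, among them H19, Meg3, Atp4b, Gkn1, Gkn2, Muc5ac and Tff1, were not analysed here. The chi-square per degree of freedom between libraries of the same group was 8.63 to 132.55, so no library repeated another within sampling noise. Values of 0 allow up to 3 reads, which is 1.84 to 5.30 normalized counts depending on the library and covers counting error only.

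Genes with a normalized count of at least 10 in at least 4 libraries were tested, which left 14220. The log2 of the normalized count plus 1 was fitted with limma 3.58.1 (trend, not robust) in R 4.3.3, with all 16 libraries in a single fit and a coefficient per genotype. The 6 comparisons between groups and the interaction of both losses were contrasts of that fit, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. The levels of Daxx and Men1 were also compared with an exact permutation test over 70 assignments. Gene lists, 38 in all, were fixed before the data were examined, and the 36 with at least 5 tested members were tested with camera at its preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were companions. Of 91 list calls at the preset correlation, 0 held with an estimated correlation and 0 with fry. The tests of the comparisons and the rule for naming genes were also set before the data were examined, as were the alternatives other than those given below as chosen later, while some tests of explanations were chosen after the result was seen.

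Named were Daxx and Men1, and per comparison the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 50 normalized counts, no overlap between the groups and an established symbol. Named too were up to 3 members past the threshold of each list described and, where a list had none, up to 2 of its most abundant members as values. Where fewer than 5 genes qualified, the 5 with the smallest p were named, as they were for the interaction. Tff2 in MC against WT, Obp2b in MC against WT and the genes in the clock gene level were chosen after their values were seen.

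On simulated counts for MC against WT over 14218 genes, limma recovered 77% of genes changed 2-fold and 97% of those changed 4-fold, with 5.4% of 184 calls false. There edgeR 4.0.16 recovered 78% and 98% with 5.4% of 186 calls false, and DESeq2 1.42.0 79% and 97% with 10.7% of 197 calls false. The simulated genes varied independently, with a dispersion set by their mean alone. The variation that genes share across the real libraries was absent, so these rates need not hold for the real data. Overlaps between comparisons that share WT libraries were set beside 100 simulations of unchanged groups and the 6 ways of giving each comparison 2 of the 4 WT libraries. Alternatives covered the pseudocount, the filter, the scaling, robust and weighted fits, fits with only the compared groups, edgeR and DESeq2 on recovered reads, a block on the replicate number, leaving out each library, and the distance around the floxed loci. Covariates for Y-linked, lymphoid and clock gene levels, and a fit without WT libraries 2 and 3, were chosen after seeing the data.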

Results

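Total RNA was sequenced from the pancreas of adult mice in which chronic pancreatitis had been induced with caerulein, a cholecystokinin analogue that overstimulates acinar cells. The 16 libraries formed 4 genotype groups of 4 animals. WT mice were wild type, DC mice carried floxed alleles of Daxx with the Pdx1-Cre transgene, MC mice carried floxed alleles of Men1 with Pdx1-Cre, and DMC mice carried both floxed genes with Pdx1-Cre. Daxx encodes a chaperone of the histone variant H3.3 and Men1 encodes menin, a scaffold of chromatin complexes. Pdx1-Cre recombines in cells of the pancreatic epithelium. Every animal had received caerulein, so each comparison is between genotypes in injured pancreas, and the WT label names no Cre transgene. Reads recovered from the deposited values came to 13481063 to 23728309 per library, and the 10 most abundant genes took 33.5% to 51.8% of them.

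Men1 transcripts were reduced in both groups that carry its floxed alleles, whereas the decrease of Daxx did not pass the test. Men1 (ENSMUSG00000024947.16, chromosome 19, 6334979 to 6340891, GRCm38) had 368 ± 61.3 normalized counts in WT (SD, n = 4), 132 ± 13.3 in MC and 168 ± 10.6 in DMC. Men1 therefore stood at 35.8% of WT in MC (limma adjusted p = 6.16e-05) and 45.6% in DMC (limma adjusted p = 0.000713). The exact permutation test of Men1 gave p = 0.0286 for each, two-sided, the smallest that 70 assignments allow. Daxx (ENSMUSG00000002307.15, chromosome 17, 33909414 to 33915590) had 263 ± 65.0 counts in WT, 223 ± 15.6 in DC, 246 ± 26.1 in MC and 182 ± 30.4 in DMC. Daxx was at 84.9% of WT in DC (limma adjusted p = 0.683, exact permutation p = 0.343) and 69.1% in DMC (limma adjusted p = 0.193, exact permutation p = 0.0571). A count over the whole gene does not show whether the floxed exons of Daxx were removed, and whole pancreas also holds cells in which Cre does not act.

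**Figure D1:**
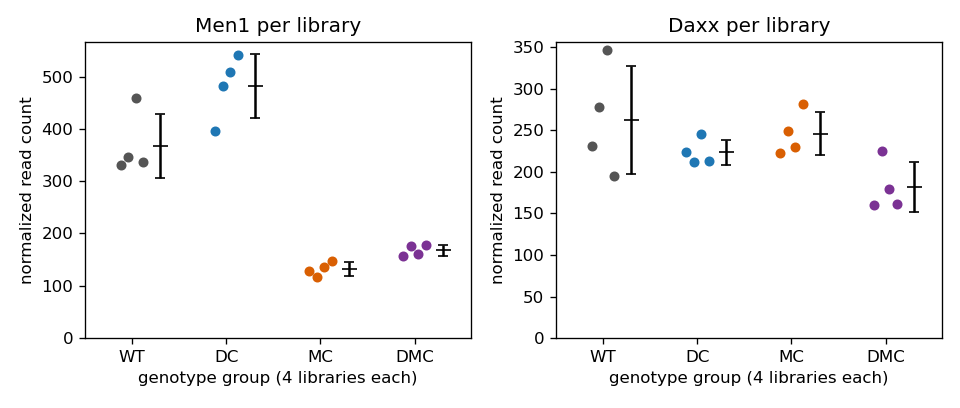
Normalized read counts of Men1 and Daxx (vertical axis) in each of the 16 libraries by genotype group. Points are libraries and the bars beside them give mean ± SD of 4; Men1 lies between 116 and 178 in the 8 MC and DMC libraries and between 331 and 541 in the other 8, while the Daxx values of the groups overlap.

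Loss of Daxx alone was addressed by DC against WT, where 3 genes rose and none fell. Obp2b, an odorant binding protein gene (chromosome 2, 25737009 to 25740097), rose from 13.3 ± 6.17 to 200 ± 61.1 normalized counts (SD, n = 4), a log2 change of 3.85 ± 0.54 (SE, limma adjusted p = 0.0135). Bglap3, a gene of the osteocalcin family (chromosome 3, 88368616 to 88372743), rose from 63.1 ± 26.1 to 504 ± 203 (limma adjusted p = 0.00993), and Ajuba, a LIM domain gene that acts in Hippo signalling (chromosome 14, 54567472 to 54577558), rose from 105 ± 26.8 to 294 ± 29.1 (limma adjusted p = 0.00993). Bglap3 belongs to a family of near-identical copies, and how reads shared between them were counted is not given, so its values are uncertain. In DMC against WT, where Daxx is floxed too, Ajuba also rose (log2 change 1.11) but Obp2b fell (-2.49). Bglap3 rose in DMC (5.47) but also in MC against WT (2.74), where Daxx is not floxed. Obp2b thus did not follow the floxed Daxx alleles across the groups. Bglap3 was higher with them both in DC against WT and in DMC against MC, but it was not raised by them alone. Next by p came Neto1 with a log2 difference of 3.24 (limma adjusted p = 0.0666) and Pcdh11x with 3.38 (limma adjusted p = 0.0793), neither past the threshold. Fibrillar collagen and matrix genes lay higher as a group: 38 of 39 had a positive log2 difference, with a median of 0.77, and 33 were higher when adjusted over the list alone, against 0 over all genes. Col3a1 averaged 22470 ± 5488 in DC and 12140 ± 1328 in WT (limma adjusted p = 0.152). The list passed camera at its preset correlation (adjusted p = 7.99e-27) but not otherwise (adjusted p = 0.308 with an estimated correlation). Fibroblast and stellate cell genes were positive in 26 of 28 members, with a median of 0.55 (camera adjusted p = 1.81e-07). Mesothelial genes were positive in 9 of 10, with a median of 0.69 (camera adjusted p = 0.000181). Endothelial genes were positive in 18 of 20, with a median of 0.35 (camera adjusted p = 0.000162). None of these 3 lists passed with an estimated correlation (adjusted p = 0.625 each). Adjusted over the list alone 6, 3 and 1 members were higher, against 0 over all genes. DC replicate 1 was the highest DC library for these lists, and without it the medians were 0.32, 0.27 and 0.18, the endothelial call being lost. With library quality weights they were 0.36, 0.17 and 0.14, the mesothelial and endothelial calls being lost. Higher levels than in WT were not particular to DC. Collagen levels (mean log2 less the mean over all 16 libraries) were -0.519 to -0.32 in WT and -0.107 to 0.928 in DC. They were -0.041 to 0.466 in MC and -0.544 to 0.127 in DMC. Fibroblast levels were -0.568 to -0.266 in WT, -0.516 to 0.786 in DC, -0.408 to 0.558 in MC and -0.347 to 0.37 in DMC. Mesothelial levels were -0.88 to -0.137, -0.593 to 1.495, -0.363 to 0.158 and 0.139 to 0.607. Acinar digestive enzymes lay lower, with a median of -0.56 and 0 of 28 members past the threshold (camera adjusted p = 0.000162; adjusted p = 0.643 with an estimated correlation). That median of acinar enzymes was -0.37 without DC replicate 1 and -0.95 without WT libraries 2 and 3, and the call was lost with quantile scaling (-0.04) and library quality weights (-0.17). All 9 neutrophil genes were positive, 3 of them higher adjusted over the list alone (camera adjusted p = 0.000181; adjusted p = 0.308 with an estimated correlation), with a median of 0.77 that was 1.28 without WT libraries 2 and 3 and 1.16 with no filter. T and NK cell genes had a median of -1.04 and 0 members past the threshold (camera adjusted p = 0.00129; adjusted p = 0.685 with an estimated correlation). WT libraries 2 and 3 stood apart with lymphoid marker levels of 8.07 and 9.03 (mean log2), against 4.17 to 7.07 in DC. The T and NK cell median turned to 0.56 without both of these, and was -0.34 without WT replicate 3, -0.62 without WT replicate 2, -0.72 without DC replicate 4, each with the call lost, and -1.71 without WT replicate 1. It was -2.05 with library quality weights, and with the lymphoid level as covariate the call was lost (0.06). A clock gene level, the mean log2 of Nr1d1, Nr1d2, Dbp, Tef and Per3 less that of Arntl, Npas2 and Nfil3, was 2.13 to 3.59 in DC and -0.48 to 2.28 in WT. These ranges hardly overlap, so a covariate of this level stands largely for genotype. Calls lost with it cannot tell clock level and genotype apart. With that level as covariate, chosen after seeing the data, limma called 0 genes, with log2 changes of 4.21 for Obp2b and 3.11 for Bglap3 (limma adjusted p = 0.167 each) and 1.28 for Ajuba (limma adjusted p = 0.178). The acinar enzyme list then lost its call (median -0.28, camera adjusted p = 0.102), and the medians were -2.25 for T and NK cell genes and 1.03 for mesothelial genes. At unadjusted p under 0.05 limma counted 1665 genes where chance gives 711, edgeR called 3 and DESeq2 281. With WT libraries 2 and 3 left out, chosen after seeing the data, 41 genes passed. Leaving out a single library gave 0 without WT replicate 4 or DC replicate 2, 1 without DC replicate 1, 5 without WT replicate 1 or MC replicate 4, 7 without DC replicate 4 and 19 without WT replicate 3.

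**Figure D2:**
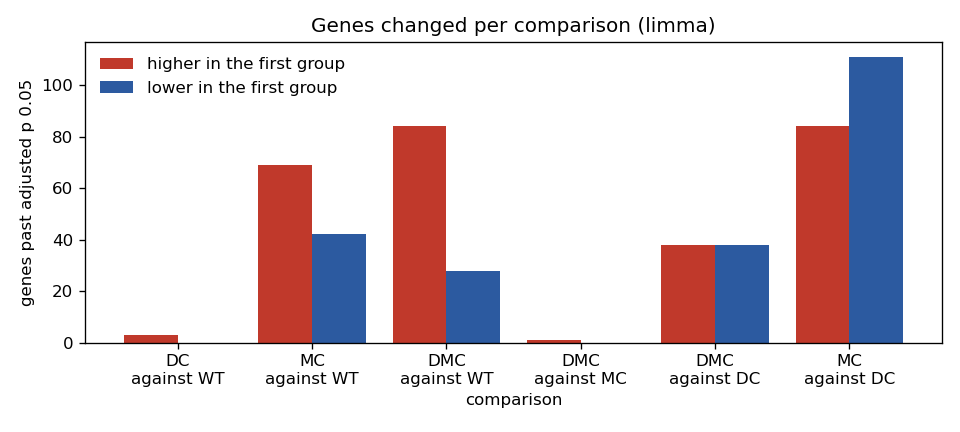
Number of genes past limma's adjusted p threshold (vertical axis) in each of the 6 comparisons, split by direction. MC against DC had the most, with 84 higher and 111 lower, and DMC against MC had 1.

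Loss of Men1 alone was addressed by MC against WT, where genes of the gastric glands rose. Cym, the gene of the milk-clotting protease chymosin (chromosome 3, 107211293 to 107221732), rose from 3.08 ± 4.15 normalized counts in WT (10 reads in all 4 libraries) to 3483 ± 4284 in MC (SD, n = 4), a log2 change of 9.67 ± 0.88 (SE, limma adjusted p = 6.16e-05). The pepsinogen genes Pga5 and Pgc rose by 4.36 and 3.82 in log2, the intrinsic factor gene Gif by 4.18, the gastrokine gene Gkn3 by 5.02, the gland mucin Muc6 by 4.29, the sodium-proton exchanger Slc9a4 by 4.17 and the ghrelin gene Ghrl by 4.75, with limma adjusted p from 0.00947 to 0.0431. Among the genes that fell were Tdh, for threonine dehydrogenase (1471 ± 969 to 112 ± 17.99, limma adjusted p = 0.000526), Nat8, Susd3, Ccbe1, Bdh1, Zc3h12b, Rftn2 and Galnt6, with log2 changes from -3.44 to -1.62. Altogether 69 genes rose and 42 fell of 14220 tested. Of the gastric metaplasia and mucin list, 4 of 14 members rose, 7 when adjusted over the list alone, and all 14 had a positive log2 difference (median 1.36; camera adjusted p = 1.31e-08; adjusted p = 0.405 with an estimated correlation). Tff2, a trefoil peptide gene in that list, was abundant in both groups, at 22580 in WT and 25380 in MC (limma adjusted p = 0.749). Gli1, the transcriptional effector of Hedgehog signalling, rose from 16.8 ± 4.19 to 78.4 ± 22.5 (limma adjusted p = 0.00723), the imprinted gene Mest from 157 ± 11.6 to 456 ± 222 (limma adjusted p = 0.0317) and the Wnt antagonist gene Sfrp1 from 263 ± 42.2 to 593 ± 180 (limma adjusted p = 0.0485). All 39 interferon-stimulated genes were positive, with a median of 1.04; 12 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 6.12e-15; adjusted p = 0.405 with an estimated correlation). Their median was 0.67 without WT replicate 1 and 1.75 without WT libraries 2 and 3. Islet endocrine genes other than hormones were positive in 32 of 33 members with a median of 1.04, 0 past the threshold (camera adjusted p = 1.62e-09; adjusted p = 0.443 with an estimated correlation). B cell and plasma cell genes had a median of -2.02 (camera adjusted p = 6.75e-06; adjusted p = 0.443 with an estimated correlation), beside lymphoid marker levels of 3.52 to 9.03 in WT and 3.39 to 6.37 in MC. The B cell median was -3.05 without WT replicate 1 and -1.25 with the clock gene level as covariate, and the list lost its call with the lymphoid level as covariate (-0.07) and without WT libraries 2 and 3 (-0.41). The count of 111 fell to 38 without MC replicate 4, 43 without MC replicate 2, 47 without MC replicate 1, 49 without WT replicate 2 and 62 without WT replicate 3, and rose to 189 without DC replicate 1. It was 59 with the lymphoid level and 44 with the clock gene level as covariate, both chosen after seeing the data.

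**Figure D3:**
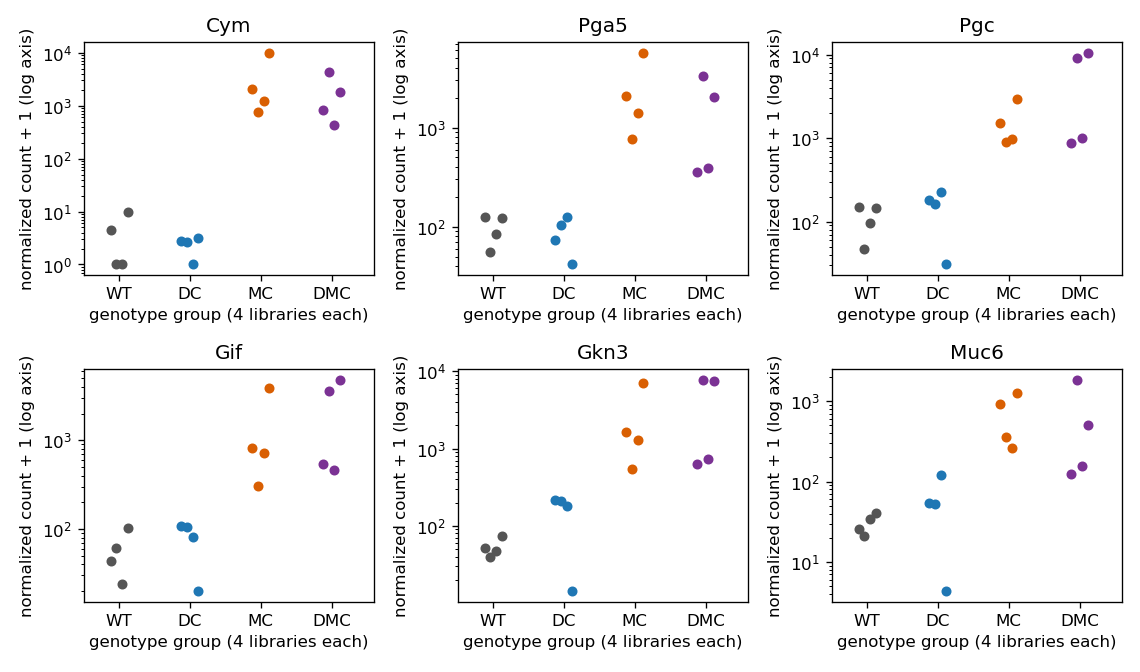
Normalized counts plus 1 of 6 stomach gland genes (vertical log axes) in each library, by genotype group; each point is a library. For Cym the 8 MC and DMC libraries lie between 427 and 9856 counts and the 8 WT and DC libraries at 8.78 or below.

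Loss of both genes was addressed by DMC against WT, where stomach gland genes and Bglap3 rose. Cym rose by 8.96 ± 0.88 in log2 (SE, limma adjusted p = 0.000118), Gkn3 by 5.44, Pgc by 4.92, Gif by 4.83, Ghrl by 4.41 and Slc9a4 by 3.71. The DMC libraries were far apart in these genes: replicates 2 and 4 had 7697 and 7444 normalized counts of Gkn3, 8974 and 10440 of Pgc and 3567 and 4790 of Gif, against 627 and 733, 880 and 1002, and 539 and 456 in replicates 1 and 3. DMC replicates 1 and 3 had high Y-linked expression, with Ddx3y at 1091 and 842.6 normalized counts. In replicates 2 and 4 it was low, at 6.09 and 0.914. Libraries with high Y-linked expression numbered 2 of 4 in WT, 1 of 4 in DC and 2 of 4 in MC, so every group mixes sexes, which the labels do not give. With the Y-linked level as covariate, chosen after seeing the data, the 6 log2 changes were 9.01, 5.50, 4.96, 4.88, 4.48 and 3.74, all past the threshold. Leaving out DMC replicate 4 ended the calls of Gkn3 (4.87), Pgc (4.32), Gif (4.25), Ghrl (3.76) and Slc9a4 (3.41). Without DMC replicate 2 those of Gkn3 (4.85), Gif (4.39), Ghrl (4.10) and Slc9a4 (3.16) ended. So did those of Gkn3 (5.40), Gif (4.47), Ghrl (4.29) and Slc9a4 (3.65) without WT replicate 3, Gkn3 (5.61) and Slc9a4 (3.95) without WT replicate 4, and Slc9a4 (3.43) without WT replicate 2. With only the groups compared in the fit, those of Gkn3, Pgc, Gif, Ghrl and Slc9a4 ended (limma adjusted p = 0.0567 to 0.0775). The same 5 ended without WT libraries 2 and 3, chosen after seeing the data (limma adjusted p = 0.0792 to 0.128). A block on the replicate number ended those of Gkn3 (limma adjusted p = 0.063) and Slc9a4 (limma adjusted p = 0.0659). Only Cym kept its call in each of these fits. Bglap3 rose from 63.1 ± 26.1 to 2866 ± 1218 normalized counts (SD, n = 4), a log2 change of 5.47, and the serpin gene Serpina5 from 6.14 ± 3.55 to 106 ± 64.4 (limma adjusted p = 0.0114). Th, for tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, rose from 9.49 ± 6.57 to 80.4 ± 42.6 (limma adjusted p = 0.0267), and Gli1 (limma adjusted p = 0.00849), Mest (limma adjusted p = 0.0417) and Ajuba (limma adjusted p = 0.0199) also rose. Among genes that fell were Thbs4, the tight junction gene Cldn6, Nat8, Slc7a3, Pde8b, Eci3, Rftn2 and Ctrl, a chymotrypsin-like digestive protease that went from 441500 ± 165000 to 113500 ± 31390 (limma adjusted p = 0.04). In total 84 genes rose and 28 fell. Ctrl was the only one of 28 acinar digestive enzymes past the threshold, and the list did not pass camera (adjusted p = 0.0693). Of the gastric list 3 of 14 members rose, 6 adjusted over the list alone (camera adjusted p = 4.44e-07; adjusted p = 0.492 with an estimated correlation). Islet endocrine genes other than hormones were positive in 32 of 33 members with a median of 1.51, 19 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 2.92e-14; adjusted p = 0.492 with an estimated correlation). Of islet hormones, Ghrl rose and the other 7 did not pass (camera adjusted p = 0.00534; adjusted p = 0.492 with an estimated correlation). The median of islet hormones, 1.26, was 0.84 without DMC replicate 4 and 0.80 without WT replicate 3, where the call was lost, as it was without WT libraries 2 and 3 (0.98) and with library quality weights (0.95). Endoplasmic reticulum stress genes had a median of -0.32, with 1 of 30 lower adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.492 with an estimated correlation). The count of 112 fell to 17 without DMC replicate 4, 32 without WT replicate 3, 33 without DMC replicate 2, 36 without WT replicate 4, 50 without DMC replicate 1 and 73 without WT replicate 2, and rose to 183 without DC replicate 1. With only the groups compared in the fit it was 16, and with WT libraries 2 and 3 left out, chosen after seeing the data, 43.

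**Figure D4:**
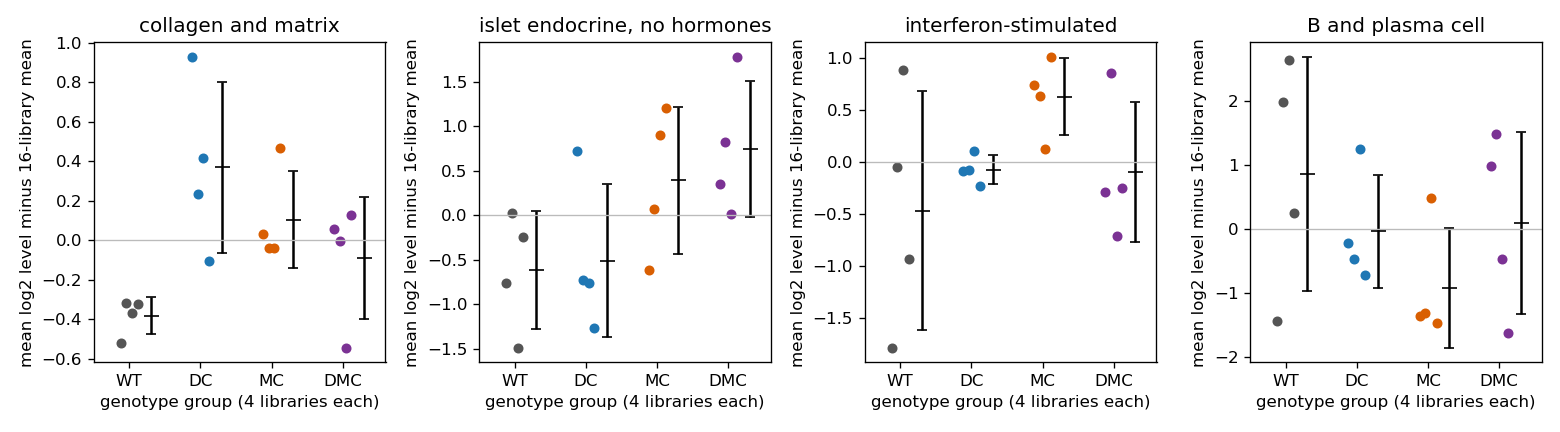
Mean log2 level of 4 gene lists per library, less the mean over all 16 libraries (vertical axis), by genotype group. Points are libraries and bars give mean ± SD of 4; the 4 WT libraries lie between -0.52 and -0.32 for collagen and matrix genes, and B and plasma cell genes span -1.43 to 2.63 within WT.

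What Daxx loss adds to Men1 loss was addressed by DMC against MC, where only Bglap3 passed. Bglap3 rose from 434 ± 183 in MC to 2866 ± 1218 normalized counts in DMC (SD, n = 4), a log2 change of 2.73 ± 0.39 (SE, limma adjusted p = 0.0441). Tdh lay higher, at 660 ± 144 against 112 ± 17.99, just short of the threshold (limma adjusted p = 0.0509), followed by Gm10036, Wdfy1 and 9030025P20Rik (limma adjusted p = 0.058 each). Gm10036 had 3.14 ± 1.42 counts in DMC and 430 ± 162 in MC, and among WT libraries 547 in replicate 4 against 3.54 to 8.16 in the others. Interferon-stimulated genes were negative in 35 of 39 members with a median of -0.68 (camera adjusted p = 5.47e-13; adjusted p = 0.767 with an estimated correlation), and adipocyte genes positive in 22 of 23 with a median of 1.18 (camera adjusted p = 1.42e-12; adjusted p = 0.767 with an estimated correlation). No member of either list passed, over all genes or adjusted over the list alone. The adipocyte median was 0.72 without DMC replicate 1 and 1.78 without DMC replicate 4, 1.90 with library quality weights and 0.75 with the clock gene level as covariate, with which the interferon-stimulated median was -1.19. At unadjusted p under 0.05 limma counted 792 genes, where chance gives 711; edgeR called 1 gene and DESeq2 56. The count was 0 without WT replicate 3, DC replicate 2, DC replicate 3 or any of the MC or DMC libraries, and 2, 3, 7 and 19 without DC replicate 4 and WT replicates 2, 1 and 4. Of alternatives chosen after seeing the data, the clock gene level as covariate gave 0 genes, the Y-linked level 2, the lymphoid level 4 and leaving out WT libraries 2 and 3 gave 9.

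What Men1 loss adds to Daxx loss was addressed by DMC against DC. Cym rose from 1.42 ± 0.976 to 1841 ± 1755 normalized counts (SD, n = 4; limma adjusted p = 6.35e-05), Pgc by 4.65 in log2, Gif by 4.46 and Pga5 by 3.62. Hal, for histidine ammonia-lyase, rose from 8.22 ± 6.52 to 478 ± 254 (limma adjusted p = 0.00422), but was also 146 to 293 in WT replicates 1, 2 and 4 and 8.97 in WT replicate 3. The deiodinase gene Dio1 rose from 5.91 ± 4.40 to 144 ± 61.0 (limma adjusted p = 0.0107), and Serpina7 and Serpina5 rose by 3.85 and 3.83 in log2. Obp2b fell from 200 ± 61.1 to 1.70 ± 1.32 (limma adjusted p = 3.51e-05), and Gprc5a, Bdh2, Thbs4, Ccbe1, Men1, Slc28a3 and Rsad1 fell by less. Lgr5, a stem cell marker and R-spondin receptor, rose from 9.24 ± 7.66 to 75.8 ± 12.9 (limma adjusted p = 0.0289), Notch1 fell from 3365 ± 1059 to 1500 ± 330 (limma adjusted p = 0.0304), and Glp1r, the incretin receptor of beta cells, rose from 584 ± 23.0 to 1123 ± 266 (limma adjusted p = 0.0266). Altogether 38 genes rose and 38 fell. Besides Glp1r, 32 of 33 islet endocrine genes were not past the threshold over all genes and 14 were higher adjusted over the list alone (camera adjusted p = 5.86e-13; adjusted p = 0.606 with an estimated correlation). Collagen and matrix genes had a median of -0.48, with 7 of 39 lower adjusted over the list alone (camera adjusted p = 2.86e-11; adjusted p = 0.606 with an estimated correlation). The collagen median was -0.30 without DC replicate 1, -0.32 without DMC replicate 3 and -0.25 with library quality weights. The count of 76 fell to 14 without DC replicate 3, 20 without DC replicate 2, 22 without DC replicate 4, 23 without DMC replicate 4, 45 without DMC replicate 3 and 48 without DMC replicate 1, and rose to 188 without DC replicate 1 and 115 without WT replicate 3. Of alternatives chosen after seeing the data, the clock gene level as covariate gave 7 genes, the lymphoid level 133 and leaving out WT libraries 2 and 3 gave 117.

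The single losses were set against each other in MC against DC, where both groups carry Cre and 84 genes rose and 111 fell. Cym, Hal, Pga5, the protease gene Tmprss13, Muc6, the cytochrome gene Cyp2c70, Gif and Ghrl were among the genes that rose in MC, with log2 changes from 3.81 to 9.89, though Hal was also 146 to 293 in WT replicates 1, 2 and 4. Obp2b fell from 200 ± 61.1 to 0.725 ± 1.45 normalized counts (SD, n = 4; 984 reads in DC and 4 in MC, limma adjusted p = 5.25e-06). Gprc5a, Bdh2, Tdh, Susd3, Cd209a, Zbtb16, a transcription factor induced by glucocorticoids, and Nr1d1, the clock repressor REV-ERB alpha, fell with log2 changes from -3.99 to -2.64. Reg2, a regenerating islet-derived gene, rose from 6269 ± 1635 to 65970 ± 9603 (limma adjusted p = 0.0374), Prom1 from 687 ± 19.6 to 2318 ± 680 (limma adjusted p = 0.0237) and the interferon-stimulated Cmpk2 from 146 ± 22.0 to 365 ± 66.9 (limma adjusted p = 0.00192). Ajuba fell from 294 ± 29.1 to 103 ± 19.14 (limma adjusted p = 0.00184), Notch1 from 3365 ± 1059 to 1432 ± 212 (limma adjusted p = 0.0163) and Herpud1, of endoplasmic reticulum associated degradation, from 17240 ± 4854 to 7388 ± 794 (limma adjusted p = 0.0313). Gastric list genes rose in 3 of 14 members, 7 adjusted over the list alone (camera adjusted p = 4.25e-06; adjusted p = 0.852 with an estimated correlation). Of the ductal list 8 of 30 were higher adjusted over the list alone and 1 over all genes (camera adjusted p = 0.000579; adjusted p = 0.91 with an estimated correlation). Of the adipocyte list 9 of 23 were lower adjusted over the list alone and 0 over all genes (camera adjusted p = 4.44e-09; adjusted p = 0.91 with an estimated correlation). Libraries of these groups also stood apart in the clock gene level, which was 2.13 to 3.59 in DC and -0.79 to -0.18 in MC. The ranges do not overlap, and the level is built from genes that differ between these groups, such as Nr1d1. A covariate of it is thus close to the group label, and calls lost with it cannot tell clock level and genotype apart. With that level as covariate, chosen after seeing the data, 4 genes passed instead of 195, and the ductal (median 0.08) and adipocyte (median -0.37) lists lost their calls. The count fell to 49 without DC replicate 2, 50 without DC replicate 4, 65 without MC replicate 2, 81 without MC replicate 1, 83 without DC replicate 3 and 118 without MC replicate 3.

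Whether losing both genes differed from the sum of the single losses was tested as an interaction, and no gene passed. The smallest p belonged to Steap3 and Raet1e (limma adjusted p = 0.0817 each), then Itgbl1, Gm4737 and Fgfr3 (limma adjusted p = 0.27 each). Steap3 averaged 173 ± 12.8 in DMC and 177 ± 26.0 in WT, and Raet1e 3.33 ± 1.57 and 15.2 ± 11.04. Gm4737 parted the WT libraries, with 33.6 and 34.4 in replicates 1 and 2 and 1535 and 2004 in replicates 3 and 4. At unadjusted p under 0.05 limma counted 1156 genes where chance gives 711, edgeR called 0 and DESeq2 43. Leaving out WT replicate 4 gave 8 genes, WT replicate 3 gave 6, WT replicate 1 gave 2 and MC replicate 3 gave 1; chosen after seeing the data, the Y-linked level as covariate gave 1 and leaving out WT libraries 2 and 3 gave 5. Genes past the threshold in some of the comparisons and not in others are thus not shown to respond differently to the other loss.

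The lists of genes changed in MC and in DMC against WT shared 43 genes that rose and 15 that fell, Cym, Gkn3, Pgc, Gif, Ghrl, Slc9a4, Nat8 and Rftn2 among them. Independent lists of those sizes would share 0.408 and 0.0827, and unchanged groups simulated against a common control group shared 0. Simulated groups and controls were drawn from the residuals of all 16 libraries, so the spread particular to the WT libraries was not kept. In a separate simulation of counts, limma made 0 calls in an unchanged DC against WT. Comparisons with hardly any calls can share none, so a shared count of 0 gives no chance value for the shared genes. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.733 and covariance 0.209. In the 100 simulations with a common control group the mean r was 0.453 and the covariance 0.0607 ± 0.0449 (SD). The simulated r ranged from -0.278 to 0.849, which includes the r seen. With the WT libraries split between the comparisons, r was 0.0674 to 0.497. DC and MC against WT shared Bglap3 as a gene that rose, while Obp2b rose in DC and fell in MC. Their r was 0.411, below the simulated mean, with a covariance of 0.0958, and -0.221 to 0.283 with the WT libraries split. DC and DMC against WT shared 2 genes that rose, while Obp2b rose in DC and fell in DMC. Their r was 0.428, with a covariance of 0.0984, and -0.15 to 0.301 with the WT libraries split.

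Genes beside the floxed loci were examined because such alleles often carry flanking sequence of another strain. Within 5 Mb of Daxx, 0 of 192 tested genes changed in DC against WT and 0 in DMC against WT, where 0.02% and 0.8% of the genes elsewhere changed. Within 5 Mb of Men1, 1 of 207 changed in MC against WT and 1 in DMC against WT, which was Pga5 in both. Elsewhere 0.78% and 0.79% changed. Of the 12 Fisher exact tests at this distance, two-sided, none passed after adjustment (adjusted p = 1 for each). With so few genes changed anywhere, these tests could find only a large excess, so a smaller effect of flanking sequence is not excluded.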

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

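Of the tests in this part, those for stomach tissue and for more of a cell type that raises all its genes alike were chosen only after the result was seen, while those for library scaling and for other splits of the libraries were set before.

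A library stood far from the other 3 of its group, by a gap that exceeds Dixon's critical value for its share of the group's range, in 23 of 284 groups looked at, where chance gives about 5%. Replicate 4 of MC accounted for many of these values among the stomach gland genes. In normalized counts it had 9860 for Cym (the others 768 to 2090), 7060 for Gkn3 (546 to 1640), 3850 for Gif (305 to 811), 317 for Slc9a4 (78.8 to 96.8) and 100 for Vsig1 (23.8 to 27.3). The same library had 2.9 for Obp2b, against 0 in the other MC libraries, and 92700 for Ctrl, against 193000 to 209000. Elsewhere in MC, Tmprss13 was 151 in replicate 3 (73.3 to 85.7) and Fgfr3 764 in replicate 2 (609 to 621).

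In WT, replicate 3 stood apart with 459 for Men1 (331 to 345), 17.9 for Ddit4l (50.5 to 52.4), 339 for Bdh2 (19 to 35.4) and 2220 for Reg2 (30500 to 33300). Replicate 4 of WT had 16.5 for Ghrl (5.3 to 6.33), 23.1 for Gli1 (14.1 to 15.4) and 547 for Gm10036 (3.54 to 8.16), and replicate 2 had 140 for Mest (162 to 164). In DC, Gkn3 was 13.2 in replicate 4 (181 to 213) and Zbtb46 335 in replicate 3 (269 to 276). In DMC, replicate 3 had 28.7 for Zc3h12b (44.6 to 46.6), 120000 for Reg2 (10900 to 24000) and 131 for Sgce (181 to 188), and replicate 2 had 26.4 for 9030025P20Rik (47 to 47.5).

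Several stomach gland genes, named because they passed the threshold, were raised in MC and DMC, but unevenly. Cym was at 427 normalized counts or more in each of those libraries and 8.78 or less in the others. Muc6, which passed in MC but not in DMC against WT, was 122 in DMC replicate 1 against 119 in DC replicate 3. The level of the whole gastric list was -0.17 in DMC replicate 1, below DC replicate 1 at -0.11. Library scaling is argued against, since the smaller median log2 change of Cym, Gkn3, Pga5, Pgc, Muc6 and Gif under TMM and quantile scaling was 4.23 and each gene kept limma adjusted p between 7.14e-05 and 0.0427. Stomach tissue in the dissected pancreas cannot be told apart: Atp4a, for the acid pump of parietal cells, was above the highest WT library in 5 of the 8 MC and DMC libraries. It averaged 27.3 normalized counts in MC and 48.7 in DMC against 12.5 in WT (limma adjusted p = 0.398 and 0.197), and the level that stomach tissue would bring was not measured. More of a cell type already present in WT, raising all its genes alike, cannot be told apart from new expression, because Tff2, with a log2 difference of 0.27 ± 0.29 (SE), has a WT level of 22580 that would hide a rise of the size seen. An effect of Men1 loss in pancreatic epithelium is therefore a hypothesis that stays open beside both explanations.

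The 8 libraries of a comparison were divided in all 35 ways. Only the real split gave as many as the 111 genes of MC against WT (highest other 2). The same held for the 76 of DMC against DC (highest other 0) and the 195 of MC against DC (highest other 0). That is 1 of 35 splits, the smallest share possible, and was not adjusted over the 6 comparisons, so chance was made less likely but not excluded. Chance could not be excluded either for the 3 genes of DC against WT, where 2 splits were as large and the other gave 1184. That split put WT replicates 1 and 4 with DC replicates 2 and 4, and points to a structure of the samples. The acinar digestive enzyme level, less the mean over all 16 libraries, was 0.594, 0.462, 0.09 and 0.239 there. In WT replicates 2 and 3 and DC replicates 1 and 3 it was -0.179, -0.037, -1.055 and -0.307. Lymphoid marker levels overlapped, at 3.52, 5.83, 4.34 and 4.17 against 8.07, 9.03, 4.87 and 7.07. Nor could it for the 112 of DMC against WT, where 2 splits were as large and the other, with WT replicates 1 and 4 beside DMC replicates 3 and 4, gave 821, again pointing to such a structure. For the 1 gene of DMC against MC 2 splits were as large (highest other 1), so chance could not be excluded there. For the interaction the real count was 0 (limma, 1156 genes at unadjusted p under 0.05, edgeR 0, DESeq2 43), which each of 100 drawn assignments reaches by construction (highest other 10), so they say nothing about chance.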

How the results depend on the processing

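The covariate fits and the fit without WT libraries 2 and 3 were chosen only after the result was seen; the other alternatives were set before. Counts are in the order DC, MC and DMC against WT, DMC against MC, DMC against DC, MC against DC and the interaction, and were 3, 111, 112, 1, 76, 195 and 0 with limma. Library quality weights gave 177, 265, 245, 35, 1655, 1033 and 11, with Daxx in DMC against WT at -0.62 (limma adjusted p = 0.0432). DESeq2 gave 281, 391, 331, 56, 345, 500 and 43, including all 3, 111, 112, 1, 76 and 195 genes. Only the groups compared gave 1, 67, 16 and 10 for the first 4. Fewer libraries estimate the spread in those fits, but the counts moved in both directions and the cause was not tested. A clock covariate, which overlaps closely with the DC group, gave 0 (DC against WT), 44 (MC against WT), 0 (DMC against MC), 7 (DMC against DC) and 4 (MC against DC). Without WT libraries 2 and 3 they were 41 (DC against WT), 43 (DMC against WT), 9 (DMC against MC), 117 (DMC against DC) and 5 (interaction). A lymphoid covariate gave 59 (MC against WT), 4 (DMC against MC) and 133 (DMC against DC), a Y-linked covariate 2 (DMC against MC) and 1 (interaction). A pseudocount of 10 gave 7 (DMC against MC) and 2 (interaction), a minimum of 50 gave 70 (DMC against WT) and 2 (DMC against MC), quantile scaling 10, robust eBayes 0 and leaving out Y-linked, mitochondrial and hemoglobin genes 2, all for DMC against MC. Beside these, each count under those settings and under TMM, no filter, a pseudocount of 0.5 and edgeR was within 1.5 times. Except where stated the cause was not tested.

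A block on the replicate number gave 46 for MC against WT, 36 for DMC against WT, 0 for DMC against MC, 37 for DMC against DC and 110 for MC against DC, and moved no other count by over 1.5 times. The numbers are not known to pair animals: 11 of 24 pairs correlated over 0.1, and a library correlated best with its own number in 6.

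Leaving out each library in turn gave 0 to 19 genes in DC against WT, 38 to 189 in MC against WT, 17 to 183 in DMC against WT, 0 to 19 in DMC against MC, 14 to 188 in DMC against DC, 49 to 253 in MC against DC, 0 to 8 for the interaction and 84 to 101 list calls. Each library that moved a count by over 1.5 times is named with the comparison it concerns. Log2 differences of Daxx spanned -0.34 to -0.06 in DC, -0.20 to 0.07 in MC and -0.64 to -0.37 in DMC, and of Men1 0.33 to 0.50, -1.52 to -1.36 and -1.16 to -1.01. List calls were 91, and 0 with an estimated correlation and 0 with fry.

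The sign turned for Daxx in MC against WT, 0.074 without WT replicate 3, 0.098 with the lymphoid covariate, 0.086 with the clock covariate and 0.203 without WT libraries 2 and 3, and for Daxx in DC against WT, 0.067 without those 2. The correlation of DC with MC changes turned to -0.221 with split WT libraries, which no longer share noise. Among the 91 list calls, medians turned for macrophage genes (-0.11, weights) and interferon-stimulated genes in DC against WT (-0.09 without WT replicate 1 to 0.841 without WT replicate 3, -0.446 with the clock covariate), and for the latter in DMC against WT (-0.091 to 0.837 without the same libraries). Camera's direction, not the median, turned for these in DMC against WT without DMC replicate 2 (0.009) and for islet endocrine genes in DMC against MC without DMC replicate 4 (0.039; 0.004 without MC replicate 1 to 0.731 without MC replicate 4). Medians also turned for imprinted genes in DMC against WT (-0.015 without WT replicate 3, -0.002 with the lymphoid covariate), for B cell genes (0.14) and T and NK cell genes (0.059) in DC against WT and T and NK cell genes in MC against WT (0.21) with the lymphoid covariate, and for acinar granule genes in MC against DC (-0.25) with the clock covariate. Without WT libraries 2 and 3 they turned for T and NK cell genes in DC (0.56), MC (0.39) and DMC against WT (0.70), B cell genes (0.60) and cell cycle genes (0.026) in DC against WT, embryonic pancreas genes in DC (-0.041) and DMC against WT (-0.11), and imprinted genes in DMC against WT (-0.129). The cause was not tested. For named genes other than Daxx and Men1, 0 turned sign, 2990 values kept direction and side of the threshold, 630 lost the call and 63 gained it; for lists 2605 kept and 375 lost it. No scaling moved the median of all genes by over 0.1.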

Other observations

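All clock gene, glucocorticoid and strain variant values in this part are on patterns noticed in the data, and the tests for variants that segregate in the colony, for a variant beside a floxed allele and for depth were chosen only after the result was seen; those for clock phase, glucocorticoid exposure and linked variants were set before.

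Circadian clock genes differed between MC and DC beyond Nr1d1, in genes chosen after Nr1d1 and Zbtb16 had been seen. Arntl, the activator that Nr1d1 represses, averaged 502.7 normalized counts in MC and 125.5 in DC, a log2 change of 2.03 ± 0.38 (SE, limma adjusted p = 0.0163). In the opposite direction Nr1d2 averaged 487.2 and 1874 (limma adjusted p = 0.0163), Dbp 66.63 and 245.9 (limma adjusted p = 0.0458) and Tef 496.6 and 1085 (limma adjusted p = 0.0477). Of glucocorticoid-responsive genes, Tsc22d3 fell by 1.06 in log2 (limma adjusted p = 0.0272), Errfi1 by 1.41 (limma adjusted p = 0.037) and Ddit4 by 1.05 (limma adjusted p = 0.0144), while Sgk1 differed by -0.03 (limma adjusted p = 0.974) and Mt2 by 0.35 (limma adjusted p = 0.828).

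A difference in clock phase between the collections may account for this pattern, as genes that peak opposite to Nr1d1 had a median log2 difference of 1.35 and 8 of 8 in phase with it were negative, with a median of -1.52. A difference in glucocorticoid exposure may contribute, with a median of -0.72 over 9 other responsive genes, 8 of them negative. The hour of collection is not given in the labels, so neither can be separated from genotype, and an effect of genotype on the clock stays open as untested. The clock gene level also varied within groups, from -0.48 to 2.28 in WT and from -0.68 to 3.46 in DMC. With that level as covariate, chosen after seeing the data, the count in MC against DC was 4 instead of 195, in a fit where the covariate and the DC group overlap closely.

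Cym and Obp2b were near 0 in every library of some genotypes and high in every library of another. Lower depth is argued against for Obp2b, because the fewest Obp2b reads in a DC library were 123 while MC libraries of similar depth had 0 to 4. Linked strain variants could not be settled: 47 of 195 genes changed in MC against DC lay within 1 Mb of another, against a median of 51 in 1000 random draws, but those 195 genes are a wider set than the pattern. A strain variant in the gene itself, carried beside a floxed allele, is argued against, since 0 of these genes lie on chromosome 17 or 19 with Daxx and Men1: Cym is on chromosome 3 and Obp2b on chromosome 2. Variants that segregate in the colony could not be settled either. Of 18 autosomal genes in 2 separate classes, 16 parted libraries of the same genotype, while Cym and Obp2b are the 2 that did not. Among the 16 were Hal, Gm10036, Gm4737, Trim12a, Ifi202b, Zfp990 and Eno1b, but also Glycam1 and the acinar enzyme gene Ctrc. These genes were picked from the same values, and parting a genotype does not show a strain variant, so they cannot favour this explanation.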
